A study of Mus musculus with 15 samples.

How the data were processed

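RNA was measured in 15 libraries of myeloid cells sorted by flow cytometry from 8 mouse tumours, 4 of Mock-LLC and 4 of SULT2B1b-LLC cells, 10 days after the tumours were established. LLC is the Lewis lung carcinoma line, and SULT2B1b is a sulfotransferase that adds sulfate to cholesterol and oxysterols, the natural ligands of the nuclear receptor LXR. From each tumour Ly6Chigh CD11c+ MHC-II+ cells and Ly6Clow cells were taken, except that no Ly6Clow library of SULT2B1b-LLC tumour 1 was analysed here. Per the labels' protocols, total RNA was purified on spin columns, 500 ng was used per library, libraries were made with the SMART-Seq v4 kit and reads were single-end of 75 nt from a NextSeq 500. This kit does not mark strand, so reads of a gene and of an antisense or overlapping gene cannot be told apart.

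The deposited table holds raw read counts per gene symbol, 1 column per library, with no normalization by the authors; this was read from the values, which are whole numbers whose column totals differ. The aligner STAR 2.5.3a, the counter featureCounts and the R package limma are named in the submitters' processing notes, with the builds mm10 and GRCm38, which are the same assembly. The annotation release, the counting options and the use made of limma are not given in the sources used here. The table has 50508 symbols, of which 15730 had no count in any library. Gene positions were looked up by symbol in GENCODE mouse release 21 on GRCm38, where 94.3% of the symbols were found, and are given 1-based.

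Groups were taken from the sample labels: Mock-LLC Ly6Clow (n = 4), Mock-LLC Ly6Chigh (n = 4), SULT2B1b-LLC Ly6Clow (n = 3) and SULT2B1b-LLC Ly6Chigh (n = 4). The labels number the tumours, so replicates are separate tumours, but no label says that each came from its own mouse, and p-values measure the spread between these samples. No replicate pair agreed within sampling noise: chi-square per degree of freedom between replicates ran from 20.9 to 91.2.

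Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 13800. TMM factors scaled the libraries, and a quasi-likelihood model with robust settings was fitted to the 4 groups at once, so that all libraries shared an estimate of the spread per gene. Tests were two-sided with Benjamini-Hochberg adjustment within a comparison, and the threshold was an adjusted p under 0.05. All adjusted p-values of genes come from this edgeR test unless another is named. The 5 comparisons were SULT2B1b-LLC against Mock-LLC in each population, Ly6Chigh against Ly6Clow in each tumour type, and the interaction of both. Levels are CPM, counts scaled to TMM-adjusted library sizes, as mean ± SD, and folds are fitted folds. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over the whole group; such floors and all intervals cover counting error only.

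In total 35 gene lists, 20 of cell programs and 15 of cell types, were fixed before the data were examined, together with the comparisons, the test, the rule for named genes and most other settings tried. The 28 lists with 5 or more measured members were tested with camera (limma 3.58.1, preset correlation between genes of 0.01), with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were alternatives. Members past the threshold are counted over all genes tested and also adjusted over the list alone. For the other 7 lists levels are given. Some lists share members, so their results are not independent. The complement and macrophage lists share C1qa, C1qb and C1qc.

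Named genes followed a fixed rule. It took the 8 largest changes per direction among genes past the threshold, with an average log2 CPM of 3 or more and no overlap between the 2 groups, leaving out unnamed gene models. It added up to 2 members per direction of each list, and Sult2b1, the gate genes and Trem1 in every comparison. For the interaction both genes past the threshold were named. The text gives a part of the list members that the rule named, picked after the values were seen; Alox15 and Thbs3 outside the interaction, and Ly6a in Ly6Chigh cells, were also picked then. Results for some genes are not reported here.

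Within a tumour type, libraries with the same number come from the same tumour by their labels. Their deviations from the group means correlated weakly across genes, with r from 0.0279 to 0.0936 in Mock-LLC and from -0.0103 to 0.0795 in SULT2B1b-LLC. A fit with the tumour as a block was tried for comparisons between populations. Also tried were median-ratio, upper-quartile and no scaling factors, no filter or a stricter filter, DESeq2 1.42.0, limma-voom with and without quality weights, non-robust settings, fits of only the 2 groups compared, stricter thresholds and each library left out in turn. Fits without the Ly6Chigh library of SULT2B1b-LLC tumour 1 were added after the libraries had been inspected.

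The fit was tested on simulated data for the 13800 genes, with 200 genes above a minimum mean level changed by known folds. It recovered 28% of 2-fold and 70% of 4-fold changes for the tumour comparison in Ly6Chigh cells, and 26% and 69% in Ly6Clow cells. For the populations it recovered 24% and 67% in Mock-LLC and 28% and 72% in SULT2B1b-LLC, and for the interaction 7% and 45%. False calls made up 2%, 5.94%, 1.09%, 1.96% and 1.89% of the calls in the same order. The simulation gave all libraries the same spread per gene, whereas the real Ly6Chigh replicates correlated less than the Ly6Clow ones. These rates therefore need not hold for the real libraries, and the recovery rates do not cover genes at low levels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.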

Results

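The data are transcriptomes of tumour-infiltrating myeloid cells in 4 groups, Ly6Chigh CD11c+ MHC-II+ cells and Ly6Clow cells from Mock-LLC tumours and from tumours of LLC cells carrying SULT2B1b. Depth differed between the populations: the 7 Ly6Clow libraries held 19792494 to 39284008 counts and the 8 Ly6Chigh libraries 2617878 to 10626954, with no overlap. A floor of 3 counts lay between 0.0764 CPM in the deepest library and 1.15 CPM in the shallowest. Replicates correlated at a median of 0.962 to 0.975 within the Ly6Clow groups and 0.733 to 0.865 within the Ly6Chigh groups. The Ly6Chigh library of SULT2B1b-LLC tumour 1 stood apart. It had 2617878 counts, yet 24540 genes with a count where the other Ly6Chigh libraries had 13123 to 17737, and 9.83% of its counts fell on unnamed gene models (Gm or Rik symbols) where the other Ly6Chigh libraries had 1.27% to 1.76%.

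**Figure D1:**
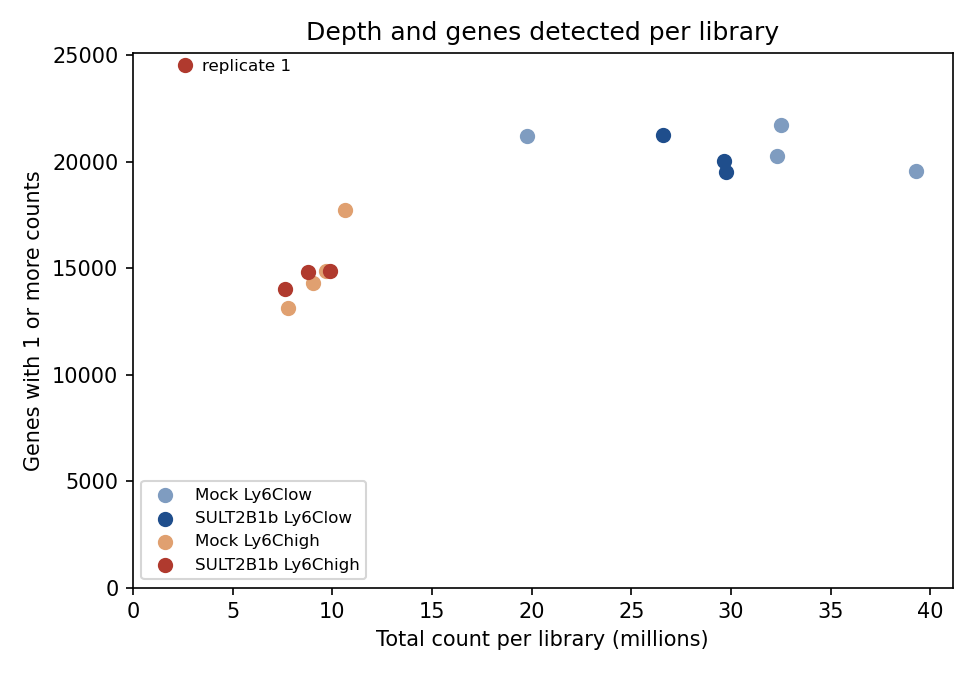
Total count per library (x axis, in M counts) against the number of genes with 1 or more counts (y axis), 1 point per library, coloured by group. The 8 Ly6Chigh libraries lie between 2.62 and 10.6 M and the 7 Ly6Clow libraries between 19.8 and 39.3 M; replicate 1 of the SULT2B1b Ly6Chigh group has the fewest counts and 24540 genes.

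Transcripts of Sult2b1 itself (chromosome 7, 45729983 to 45784669) were counted in the sorted cells. In Ly6Chigh cells the level was 12.2 ± 4.62 CPM in SULT2B1b-LLC (n = 4) against 0.162 ± 0.215 CPM in Mock-LLC tumours (n = 4), and it rose past the threshold (adjusted p = 0.0296). In Ly6Clow cells it was 1.60 ± 0.691 (n = 3) against 0.301 ± 0.220 CPM (n = 4) and did not pass (adjusted p = 1). Every SULT2B1b-LLC library, from 1.12 to 19.1 CPM, lay above every Mock-LLC library, which ran from 0 to 0.510 CPM for Sult2b1. As the LLC cells of these tumours carry SULT2B1b, RNA of tumour cells and expression by the sorted cells cannot be told apart here. Of the gate genes, those of Ly6C followed the sort, while Itgax, which encodes CD11c, did not pass between the populations in either tumour type. Ly6c2 stood at 1381 ± 374 and 1605 ± 354 CPM in Ly6Chigh cells of Mock-LLC and SULT2B1b-LLC tumours, and at 27.1 ± 7.99 and 27.5 ± 6.80 CPM in Ly6Clow cells. Ly6c1 stood at 2.64 ± 1.32 and 18.7 ± 10.9 CPM in Ly6Chigh and at 0.0960 ± 0.111 and 0.539 ± 0.409 CPM in Ly6Clow cells in the same order. Ly6c1 and Ly6c2 are near-identical copies, so the split of reads between them is uncertain. Genes used for the sort are no finding between the populations.

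The comparison of tumour types within Ly6Chigh CD11c+ MHC-II+ cells asked how these cells differ when the tumour carries SULT2B1b. The interferon-gamma-inducible chemokine gene Cxcl9 (chromosome 5, 92321347 to 92328079) stood at 236 ± 72.4 CPM in SULT2B1b-LLC against 43.1 ± 12.9 CPM in Mock-LLC tumours (n = 4 each), 5.48-fold, and the GTPase Iigp1 rose 3.85-fold. Complement component genes C1qa and C1qb rose 2.08-fold and 1.80-fold, the phospholipid transfer protein gene Pltp, an LXR target, 1.93-fold, and the sterol synthesis genes Msmo1 and Nsdhl 1.85-fold and 2.04-fold. Among the genes that fell were Spp1, which encodes osteopontin (3.25-fold lower, 663 ± 266 against 2154 ± 443 CPM), the angiogenic factor Vegfa (2.99-fold lower) and fibronectin, Fn1 (1.76-fold lower). Across the 13800 genes tested 223 passed the threshold, 123 higher and 100 lower in SULT2B1b-LLC tumours.

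Among genes past the threshold with an average log2 CPM of 3 or more and no overlap between the groups, the largest rises included, beside Cxcl9 and Iigp1, those of Pcolce (6.94-fold), the chemokine Ccl8 (6.62-fold), Olfml3 (4.71-fold), Mgst1 (3.54-fold) and Cbr2 (3.41-fold). Those that fell within these limits were led by the transcription factor Cebpb, which was 14.0-fold lower but uneven in Mock-LLC tumours (8.82 ± 2.55 against 124 ± 158 CPM). St3gal5, Znrf2, Med16, the Notch ligand Jag1, Spsb1, Runx2 and Dcaf5 fell 3.53- to 5.41-fold. Alox15, a lipoxygenase gene that acts on polyunsaturated fatty acids, rose from 0.0906 ± 0.181 to 9.48 ± 3.41 CPM (adjusted p = 5e-05). A share of 2.31% Ly6Clow cells in the gate would also give this rise. Keratin Krt8, an epithelial gene, was at 0 in all Mock-LLC libraries and at 5.09 ± 3.92 CPM in SULT2B1b-LLC tumours, at least 64.4-fold higher. Cxcr2, a neutrophil chemokine receptor, had 1 count in the 4 SULT2B1b-LLC libraries and 147 in Mock-LLC, a ratio of 112 with a 95% counting interval of 19.7 to 4440.

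In the interferon-gamma response list 7 of 25 measured members rose and 0 fell, or 12 and 0 adjusted over the list alone (adjusted p = 2.09e-16, and adjusted p = 0.00975 with an estimated correlation). The type I interferon list had 0 of 27 members past the threshold and did not pass (adjusted p = 0.177, and adjusted p = 0.75 with an estimated correlation). In the MHC class I list 4 of 16 rose (10 adjusted over the list alone), among them the immunoproteasome genes Psmb9 (1.64-fold) and Psme2 (1.45-fold), with adjusted p = 0.0315 with an estimated correlation. The cholesterol synthesis and SREBP2 target list had 2 of 22 members past the threshold, Msmo1 and Nsdhl, both higher (2 adjusted over the list alone, adjusted p = 0.0401 with an estimated correlation). The complement list had 3 of 9 higher (4 adjusted over the list alone, adjusted p = 0.0401 with an estimated correlation). As C1qa, C1qb and C1qc are also on the macrophage list, these lists do not give separate evidence in any comparison. Class II genes H2-Aa (1.64-fold) and H2-Eb1 (1.69-fold) rose, while H2-Ab1 (log2 fold change 0.58, adjusted p = 0.130) and the invariant chain Cd74 (0.57, adjusted p = 0.0845) did not pass.

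Another 11 lists passed with the preset correlation but not with an estimated one. The macrophage list had 4 of 11 members higher (adjusted p = 0.0519 with an estimated correlation), and the class II list 4 of 12 (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.174). The fibroblast list had 2 of 9, Dcn and Pdgfra (adjusted p = 0.0728), the conventional dendritic cell 1 list 1 of 9, Naaa (adjusted p = 0.0589), the LXR target list 1 of 18, Pltp (adjusted p = 0.174), and the fatty acid list 1 of 14, Acadl (adjusted p = 0.196). Another list lower in SULT2B1b-LLC tumours, that of mitochondrially encoded genes, had 5 of 7 members past the threshold, led by mt-Nd1 (1.98-fold) and mt-Nd5 (1.81-fold; adjusted p = 0.0589). No member passed in the lists of hypoxia and glycolysis (lower, adjusted p = 0.102), or in those, all higher, of cell cycle (adjusted p = 0.133), oxidative phosphorylation (adjusted p = 0.574) and mast cells and basophils (adjusted p = 0.102). The gate genes Itgax (log2 fold change -0.52, adjusted p = 0.373), Itgam (-0.17, adjusted p = 0.676), Ly6c1 (2.82, adjusted p = 0.134) and Ly6c2 (0.22, adjusted p = 0.741) did not pass, and neither did the receptor gene Trem1 (-0.85, adjusted p = 0.183).

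The SULT2B1b-LLC tumour 1 library belongs to this comparison: without it 348 genes passed, the macrophage list had adjusted p = 0.0116 and the cholesterol list adjusted p = 0.0798, both with an estimated correlation. With the preset correlation and without that library, the mast cell list had adjusted p = 0.0578 and the ribosomal protein list adjusted p = 0.0251 (adjusted p = 0.72 with an estimated one). The size of the gene set rested on the model, which shared the spread per gene with the Ly6Clow libraries, whose replicates correlated more. At an unadjusted p under 0.05 there were 2152 genes, and 870 in a fit of the Ly6Chigh libraries alone. A fit of the 8 Ly6Chigh libraries alone passed 3 genes, C1qa, Cxcl9 and Ly6a, limma-voom with quality weights passed 19, no filter 109 and DESeq2 992. Leaving out the Ly6Chigh library of Mock-LLC tumour 3 gave 120 genes, and leaving out that of Mock-LLC tumour 4 gave 358. The balance of directions moved too. It was 48 higher and 61 lower with no filter, and 94 and 99 without the Ly6Chigh library of Mock-LLC tumour 1. With limma-voom it was 142 and 59.

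The comparison within Ly6Clow cells asked the same of the other population. Cxcl9 stood at 218 ± 44.1 CPM in SULT2B1b-LLC (n = 3) against 14.4 ± 3.65 CPM in Mock-LLC tumours (n = 4), 15.1-fold, and the serpin Serpina3g rose 12.9-fold. The guanylate-binding proteins Gbp4 and Gbp5, Iigp1 and the surface genes Slamf8 and Ly6a rose 4.10- to 7.82-fold. The MHC class II genes H2-Aa (chromosome 17, 34282744 to 34287823; 6232 ± 915 against 2288 ± 210 CPM), H2-Eb1, H2-Ab1 and Cd74 rose 2.72- to 2.86-fold. Spp1 (chromosome 5, 104435118 to 104441050) fell 8.10-fold, from 3498 ± 225 to 432 ± 83.7 CPM, and Fn1 fell 2.43-fold. In total 88 genes passed, 70 higher and 18 lower in SULT2B1b-LLC tumours. The median of eosinophil genes was 31.3 to 37.1 CPM in these SULT2B1b-LLC libraries against 19.0 to 24.6 CPM in Mock-LLC ones, although Siglecf did not pass (adjusted p = 1), so a change in cell composition is not separated from changes within cells.

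Complement C3 rose 4.57-fold and the granulocyte receptor gene Csf3r 2.10-fold. Further genes that fell were the sugar-responsive transcription factor gene Mlxipl (6.33-fold), Nt5e, which encodes the ectonucleotidase CD73 (4.79-fold), the matrix metalloproteinase Mmp3 (4.75-fold), versican, Vcan (3.75-fold), the chemokine Cxcl14 (3.67-fold) and Ifitm6 (2.71-fold). In the interferon-gamma response list 18 of 25 measured members rose and 0 fell, or 24 adjusted over the list alone (adjusted p = 9.13e-07 with an estimated correlation). The class II list had 7 of 12 and the class I list 9 of 16 members higher, or 8 and 13 adjusted over the list alone (adjusted p = 5.46e-05 and adjusted p = 1.72e-05 with an estimated correlation). The type I interferon list had 1 of 27 higher, Zbp1 at 2.17-fold, or 9 adjusted over the list alone (adjusted p = 0.0138 with an estimated correlation).

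The cholesterol synthesis and SREBP2 target list had 3 of 22 higher, among them Msmo1 (1.79-fold), or 7 adjusted over the list alone (adjusted p = 7.36e-05 with an estimated correlation). LXR targets had 2 of 18 higher, among them Pltp (1.51-fold) and apolipoprotein E, Apoe (1.70-fold), or 3 adjusted over the list alone (adjusted p = 0.0174). Hypoxia and glycolysis genes were lower as a list, with the mitophagy gene Bnip3 (2.08-fold) and Pgk1 (1.69-fold) past the threshold, or 18 of 22 adjusted over the list alone (adjusted p = 0.00023). The lists of macrophages (2 of 11 higher, adjusted p = 0.00474), complement (2 of 9, adjusted p = 0.00268) and conventional dendritic cell 1 (1 of 9, adjusted p = 0.00187) passed upward, and that of monocytes downward (2 of 11, adjusted p = 0.00395), all with an estimated correlation. The second dendritic cell list passed upward with no single member past the threshold (adjusted p = 0.0392 with an estimated correlation, and 0.0536 without the SULT2B1b-LLC tumour 1 library). Without that library the tumour-associated macrophage list passed with the preset correlation (adjusted p = 0.00511, against 0.067 with it), but not with an estimated one (adjusted p = 0.154).

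Another 7 lists passed only with the preset correlation, and no member of them passed. With an estimated correlation their adjusted p-values were 0.173 for ribosomal proteins and 0.131 for mitochondrially encoded genes, both lower, 0.0878 for fibroblasts, lower, and 0.129, 0.323, 0.175 and 0.0878 for dendritic cell maturation, immediate-early genes, cell cycle, and mast cells and basophils, all higher. The genes Trem1 (log2 fold change -1.12, adjusted p = 0.358), Itgam (-0.62, adjusted p = 0.225), Itgax (0.57, adjusted p = 1), Ly6c1 (2.43, adjusted p = 1), Ly6c2 (0.02, adjusted p = 1) and Clec4e (-1.15, adjusted p = 0.153) did not pass. At an unadjusted p under 0.05 there were 516 genes where chance gives 690. That fit shared the spread per gene with the Ly6Chigh libraries, whose replicates correlated less. In a fit of the Ly6Clow libraries alone there were 2129, so the 516 do not show an effect below chance. A fit of the 7 Ly6Clow libraries alone passed 422 genes, voom 250, voom with quality weights 703 and DESeq2 193. Without the Ly6Clow library of Mock-LLC tumour 3 it was 57, and without those of SULT2B1b-LLC tumours 2, 3 and 4 it was 41, 43 and 50.

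**Figure D2:**
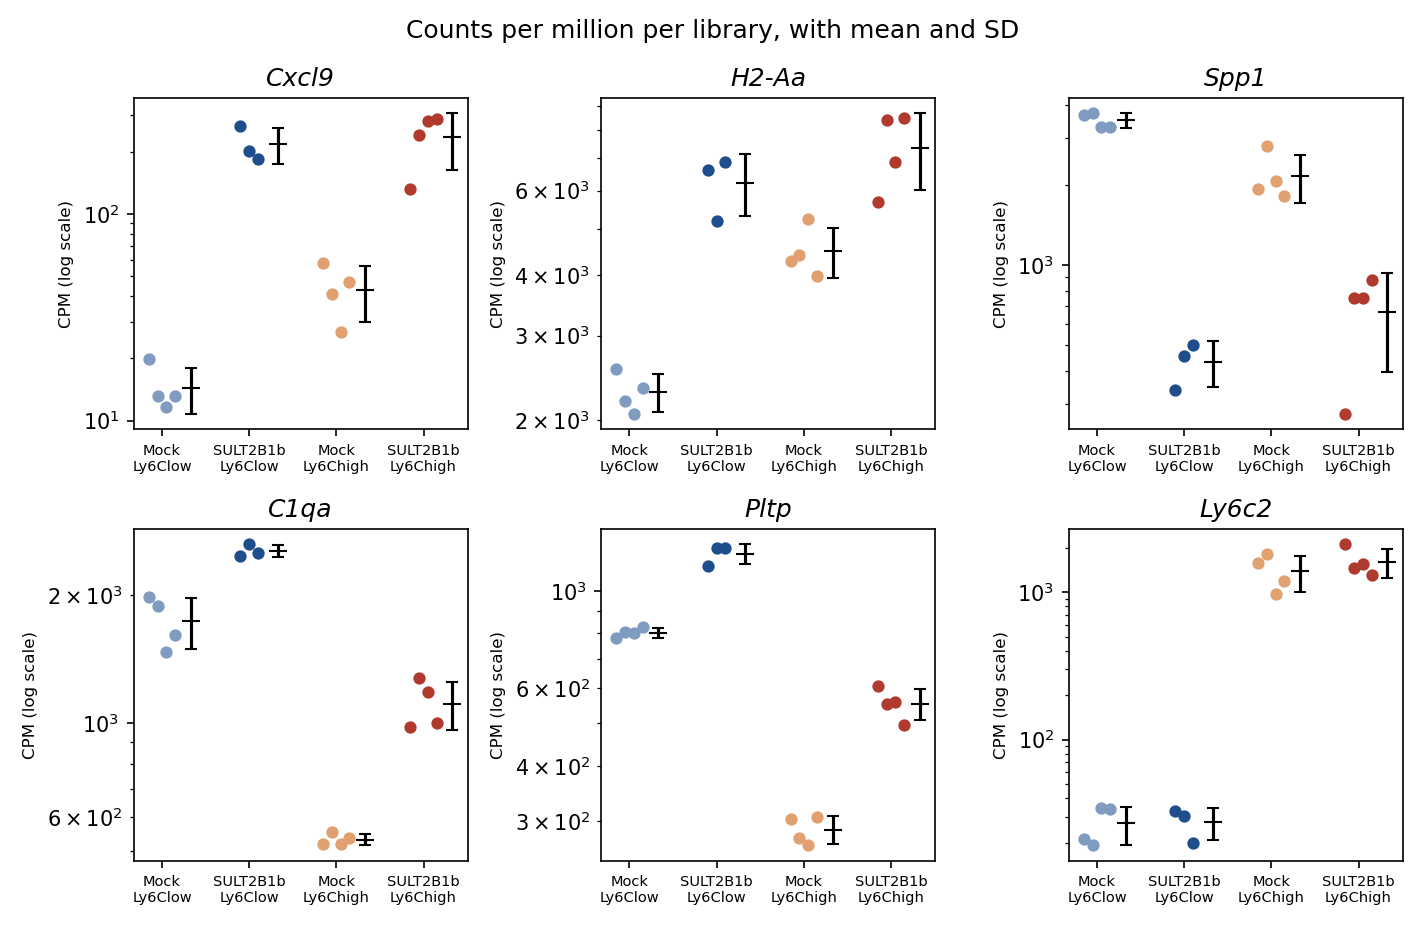
CPM on a log axis (y) for 6 genes in the 4 groups (x); each point is a library, the bar to its right the mean and SD. Cxcl9 and H2-Aa are higher and Spp1 lower in SULT2B1b-LLC tumours in both populations (Cxcl9 218 against 14.4 CPM in Ly6Clow cells), C1qa and Pltp are higher in Ly6Clow than in Ly6Chigh cells, and Ly6c2 follows the sort.

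The genes changed by tumour type overlapped between the populations, which share tumours but no library. Both sets of calls came from the same fit with a shared spread per gene. The numbers for independent lists may therefore be too low as chance values. Of the 70 genes that rose in Ly6Clow cells 28 also rose in Ly6Chigh cells, where independent lists would share 0.624; among those that fell, 7 were shared against 0.13, and 0 genes moved in opposite directions. Shared genes that rose were Cxcl9, Iigp1, Ly6a, Slamf8, Irf1, C1qa, Pltp, Msmo1 and Naaa among others, and Spp1, Fn1, Mlxipl and Cxcl14 were among those that fell. Of the 35 shared genes 7 belong to the interferon-gamma list and 7 to the MHC lists. Of the 88 genes called in Ly6Clow cells 87 had the same sign in Ly6Chigh cells, and of the 223 called in Ly6Chigh cells 173 had the same sign in Ly6Clow cells. Over all 13800 genes the correlation of log2 fold changes was low (Pearson 0.0914, Spearman 0.115, across genes, which are not independent). It was 0.221 and 0.172 over the 8735 genes with an average log2 CPM of 3 or more. Without the Ly6Clow library of SULT2B1b-LLC tumour 4 the Pearson value over all genes was -0.00688.

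**Figure D3:**
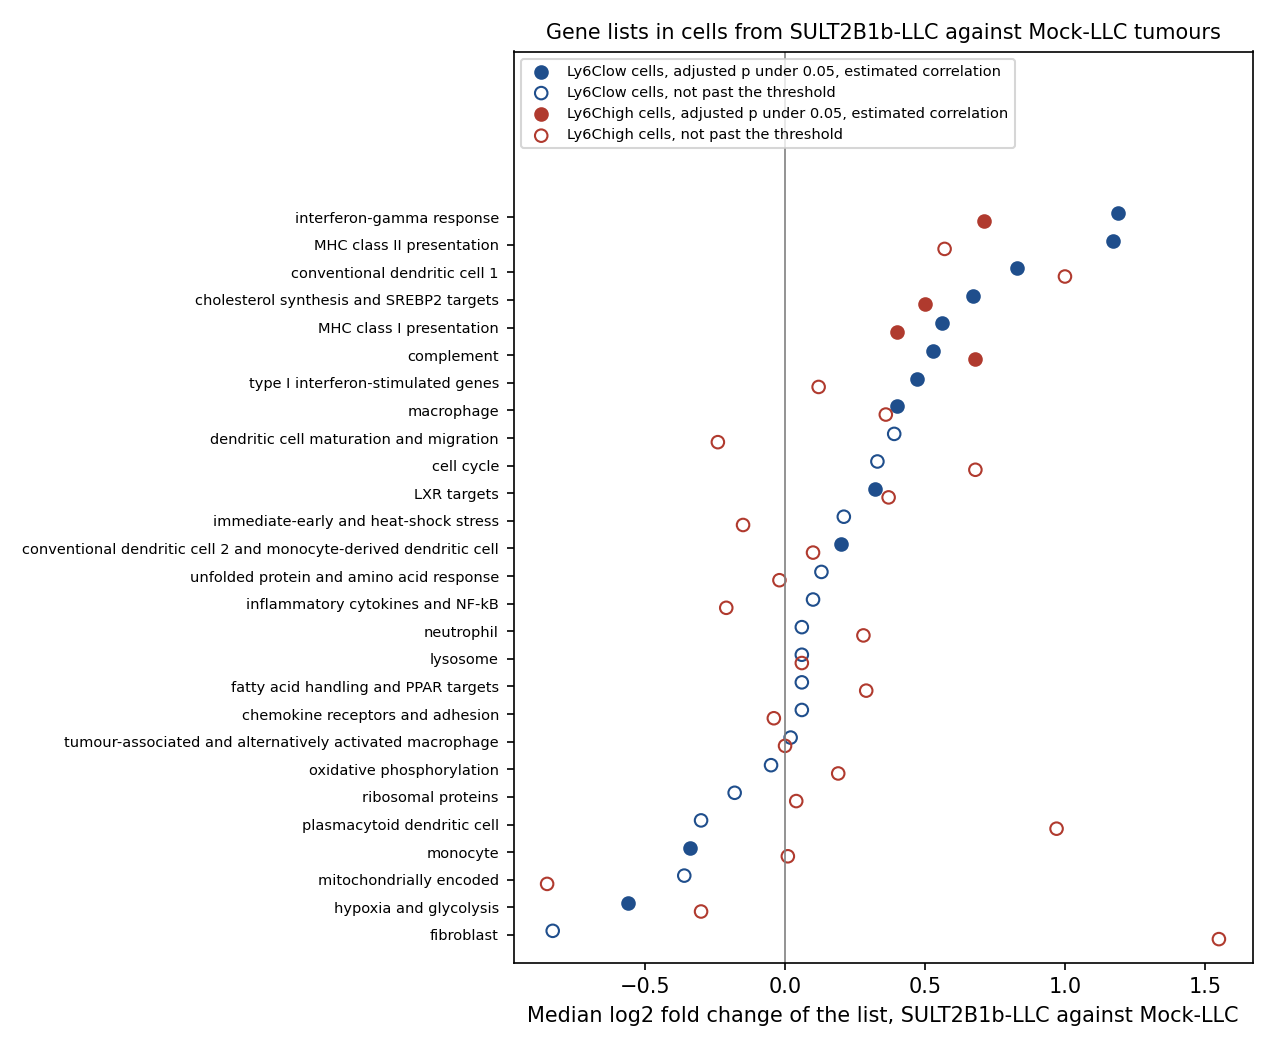
Median log2 fold change of each tested gene list between SULT2B1b-LLC and Mock-LLC tumours (x axis) in Ly6Clow (blue) and Ly6Chigh cells (red), lists on the y axis; filled points have an adjusted p under 0.05 with an estimated correlation, open points do not. The interferon-gamma list lies at 1.19 and 0.71. The mast cell and basophil list is not drawn, because 3 of its 5 members had no count in Mock-LLC Ly6Chigh cells: its fitted median in Ly6Chigh cells is 8.01, and 4.45 with these genes at their bound.

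The comparison of Ly6Chigh with Ly6Clow cells in Mock-LLC tumours asked how the sorted populations differ. Beyond the gate, Ly6Chigh cells had higher monocyte genes, such as Plac8 (743 ± 70.6 against 72.2 ± 9.39 CPM, 10.3-fold) and Ccr2 (1.49-fold), and higher interferon-stimulated genes, such as Irf7 (3.64-fold) and Rtp4 (3.61-fold). Single genes of dendritic cell lists were also higher: Cd209a (2.17-fold), Ccr7 (4.91-fold) and Cd86 (2.09-fold). Ly6Clow cells had higher eosinophil genes: Siglecf at 61.5 ± 7.87 against 0.475 ± 0.951 CPM, Ccr3 (25.7-fold higher in Ly6Clow cells) and the granule protein gene Prg2, which was at 0 in all Ly6Chigh libraries (at least 267-fold). Macrophage genes were also higher in Ly6Clow cells, such as C1qa (3.26-fold), C1qc (3.12-fold), Trem2 (2.49-fold) and Folr2 (5.39-fold), and so was Alox15, at 251 ± 39.0 against 0.0906 ± 0.181 CPM. The threshold was passed by 1160 genes, 490 higher and 670 lower in Ly6Chigh cells.

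Other large changes were Ly6i (21.3-fold), Dusp2 (9.08-fold), Pde7b (8.52-fold), the chemokine Ccl5 (7.93-fold) and Gbp4 (6.77-fold), all higher in Ly6Chigh cells. G0s2, F5, Gas6, Serpinb2, Fcna and Retnlg were 10.9- to 129-fold lower. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was 8.46-fold lower. The gene model Gm15564, which was picked after its values were seen, moved with it, at 0.267 to 0.374 of the Lars2 level in every library. Reads of another source shared by both and a change of Lars2 mRNA were therefore not told apart. All 27 type I interferon genes and 21 of 25 interferon-gamma genes rose (adjusted p = 0.000496 for each list with an estimated correlation). With an estimated correlation, the lists of monocytes (6 of 11 higher and 1, Fn1, lower, adjusted p = 0.000496), MHC class I (8 of 16 higher, adjusted p = 0.0125) and the second dendritic cell list (3 of 9 higher and 1, Mgl2, lower, adjusted p = 0.018) passed upward. So did MHC class II (7 of 12 higher, adjusted p = 0.0261), which is no finding here, since only the Ly6Chigh cells were sorted for MHC-II. The cell cycle list (11 of 28 lower, adjusted p = 0.018), with Birc5 (5.45-fold) and Mcm3 (2.39-fold), and the macrophage list (6 of 11 lower and 1, Fcgr1, higher, adjusted p = 0.0125) passed downward.

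Another 11 lists passed only with the preset correlation. Lower in Ly6Chigh cells were ribosomal proteins (12 of 34 members past the threshold, adjusted p = 0.328 with an estimated correlation), oxidative phosphorylation (5 of 28, adjusted p = 0.331), lysosome (8 of 22, such as Ctsd at 1.90-fold, with Npc2 higher, adjusted p = 0.198), tumour-associated macrophage genes (9 of 24, with Vegfa and Tgfbi higher, adjusted p = 0.0905), complement (4 of 9, with C3 and Cfb higher, adjusted p = 0.0618), fatty acid handling (4 of 14, adjusted p = 0.119) and LXR targets (3 of 18, such as Pltp at 2.80-fold, adjusted p = 0.119). Higher were dendritic cell maturation (5 of 21, adjusted p = 0.0768), mitochondrially encoded genes (5 of 7, adjusted p = 0.143), inflammatory cytokines (4 of 25 higher and 1 lower, adjusted p = 0.236) and cholesterol synthesis (4 of 22, such as Insig1 at 1.74-fold, adjusted p = 0.0835). With the tumour as a block, adjusted p with an estimated correlation was 0.0508 for MHC class II, 0.068 for MHC class I, 0.0513 for cell cycle, 0.0513 for the second dendritic cell list and 0.0442 for complement. Without the SULT2B1b-LLC tumour 1 library it was 0.018 for complement. With the block, immediate-early genes passed with the preset correlation (adjusted p = 0.0256), but not with an estimated one (adjusted p = 0.213). The lists of chemokine receptors, neutrophils, plasmacytoid dendritic cells, fibroblasts, conventional dendritic cell 1 (1 of 9 lower), mast cells, hypoxia and the unfolded protein response did not pass. Trem1 (log2 fold change 0.02, adjusted p = 0.981), Itgax (0.52, adjusted p = 0.257) and Sult2b1 (-0.77, adjusted p = 0.739) did not pass, while Itgam was 1.71-fold lower in Ly6Chigh cells.

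The balance of directions rested on the settings. With median-ratio factors 619 genes were higher and 431 lower, with the stricter filter 569 and 521, and with a fit of the 2 groups 580 and 443. Without a Ly6Clow library more were higher each time, as in 395 and 306 without that of tumour 1. With upper-quartile factors 530 were higher and 584 lower, and with limma-voom 786 and 1647. With median-ratio factors the median log2 fold change of all genes moved from -0.0756 to 0.0495. Every Ly6Clow library was deeper than every Ly6Chigh library, so depth and population are confounded. Without the Ly6Clow library of Mock-LLC tumour 1, 2, 3 or 4 the count was 701, 584, 685 or 643. Limma-voom gave 2433, DESeq2 1874 and no filter 605.

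In SULT2B1b-LLC tumours the populations differed in many of the same ways. Plac8 was 13.2-fold and Ccl5 4.48-fold higher in Ly6Chigh cells, as were the interferon-stimulated genes Ifit2 (4.91-fold) and Isg15 (3.40-fold). Siglecf (99.6 ± 12.9 against 0.862 ± 1.01 CPM), Ccr3 (16.4-fold), Alox15 (44.4-fold; 406 ± 41.9 against 9.48 ± 3.41 CPM), Retnlg (55.9-fold) and C1qc (2.65-fold) were higher in Ly6Clow cells. Of the 9 measured fibroblast genes 4 were higher in Ly6Chigh cells, among them Dcn (195 ± 59.1 against 17.9 ± 7.43 CPM), Col3a1 (9.13-fold) and Lum (15.8-fold). Thbs2 (22.8-fold), Mxra8 (14.4-fold), the collagen chaperone Serpinh1 (12.1-fold) and Mmp3 (12.6-fold) were also among the largest changes there, within the same limits on level and overlap. The threshold was passed by 365 genes, 152 higher and 213 lower, and with the tumour as a block by 210.

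The genes past the threshold in both tumour types with the same direction numbered 111 higher and 140 lower, where independent lists would share 5.40 and 10.3. As the calls share a fit and its spread per gene, these last numbers may be too low as chance values. Ly6i rose 12.3-fold, and Cd24a, Lars2, F5 and Mir6236 fell 7.07- to 25.6-fold. For Lars2 the limit given for Mock-LLC tumours holds here too. Mir6236 is annotated as a microRNA gene, and its counts need not measure the mature microRNA. With an estimated correlation, the lists of type I interferon (17 of 27 higher, adjusted p = 0.00109), monocytes (6 of 11 higher and Fn1 lower, adjusted p = 3.63e-05), interferon-gamma (3 of 25, adjusted p = 0.00924), fibroblasts (4 of 9, adjusted p = 0.00924) and the second dendritic cell list (3 of 9, adjusted p = 0.00924) passed upward. Macrophages (6 of 11 lower and Fcgr1 higher, adjusted p = 0.00924), cell cycle (5 of 28, such as Tk1 at 5.26-fold, adjusted p = 0.0276) and complement (3 of 9, adjusted p = 0.0434) passed downward. The last 2 had adjusted p = 0.0768 and adjusted p = 0.105 with the tumour as a block, and complement adjusted p = 0.0681 without the tumour 1 library, where MHC class I had adjusted p = 0.0395. Passing only with the preset correlation were MHC class I (1 of 16, B2m, higher, adjusted p = 0.0761 with an estimated correlation), inflammatory cytokines (3 of 25 higher, adjusted p = 0.386), plasmacytoid dendritic cells (0 of 7, adjusted p = 0.188), LXR targets (3 of 18 lower, such as Apoe at 2.00-fold, adjusted p = 0.0701), lysosome (4 of 22 lower, adjusted p = 0.188), tumour-associated macrophages (4 of 24 lower, adjusted p = 0.188) and fatty acid handling (0 of 14, adjusted p = 0.283).

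The class II genes H2-Aa (log2 fold change 0.24, adjusted p = 0.505), H2-Ab1 (0.24, adjusted p = 0.678), H2-Eb1 (-0.13, adjusted p = 0.784) and Cd74 (-0.13, adjusted p = 0.805) did not pass between the populations here. Neither did Itgam (-0.32, adjusted p = 0.395), Itgax (-0.56, adjusted p = 0.380), Trem1 (0.29, adjusted p = 0.779) or Sult2b1 (2.92, adjusted p = 0.255). With the block and the preset correlation, MHC class II, a gate marker (adjusted p = 0.0273), dendritic cell maturation (adjusted p = 0.0259), hypoxia (adjusted p = 0.0167) and mitochondrially encoded genes (adjusted p = 0.0366) passed upward, and fatty acid handling no longer did (adjusted p = 0.123). The first 3 had adjusted p = 0.339 each and the fourth adjusted p = 0.466 with an estimated correlation. Without the tumour 1 library and with the preset correlation, MHC class II (adjusted p = 0.0338), dendritic cell maturation (adjusted p = 0.0356), hypoxia (adjusted p = 0.00715) and mitochondrially encoded genes (adjusted p = 0.0356) passed, while lysosome (adjusted p = 0.0696), tumour-associated macrophages (adjusted p = 0.0666) and fatty acid handling (adjusted p = 0.11) did not. Those 4 that passed had adjusted p = 0.359, adjusted p = 0.359, adjusted p = 0.273 and adjusted p = 0.392 with an estimated correlation. With median-ratio factors fatty acid handling had adjusted p = 0.0718. With median-ratio factors 218 genes were higher and 151 lower, with upper-quartile factors 195 and 170, and with the stricter filter 185 and 174. The median log2 fold change of all genes moved from -0.0279 to 0.0856 with median-ratio factors. Without the Ly6Clow library of SULT2B1b-LLC tumour 2, 3 or 4 the count was 175, 135 or 127, while DESeq2 gave 887, limma-voom 652, voom with quality weights 719 and no filter 204.

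The interaction asked whether the effect of SULT2B1b differed between the populations. It passed for Alox15 (chromosome 11, 70344152 to 70352031; difference of log2 fold changes 5.66, adjusted p = 0.00362), which rose 6.36 on the log2 scale in Ly6Chigh cells and had a log2 fold change of 0.70 in Ly6Clow cells (adjusted p = 0.973). It also passed for the thrombospondin Thbs3 (chromosome 3, 89215180 to 89226837; adjusted p = 0.0402), at 0 in all Mock-LLC Ly6Chigh libraries, 10.3 ± 4.10 CPM in SULT2B1b-LLC Ly6Chigh cells (at least 130-fold higher) and 1.97 ± 0.773 and 1.85 ± 0.508 CPM in Ly6Clow cells of Mock-LLC and SULT2B1b-LLC tumours. With an estimated correlation the lists of interferon-gamma genes (median log2 fold change 0.71 in Ly6Chigh and 1.19 in Ly6Clow cells) and fibroblast genes (1.55 and -0.83) passed, both at adjusted p = 0.0496. Both had adjusted p = 0.149 without the SULT2B1b-LLC tumour 1 library. Only these 2 genes passed, with 986 at an unadjusted p under 0.05 where chance gives 690. A share of 2.31% Ly6Clow cells in the Ly6Chigh gate would give the whole rise of Alox15. The 10 genes tested for such carry-over implied a median of 3.95%, from -0.655% for G0s2 to 43.8% for Ccl8. Slight carry-over and a change within Ly6Chigh cells are thus not separated for Alox15. For Thbs3, RNA of fibroblasts or other cells was not tested as a source. With the tumour as a block 0 genes passed in edgeR (1095 at an unadjusted p under 0.05) and both lists had adjusted p = 0.221. DESeq2 passed 109 and voom 4. Leaving out the Ly6Chigh library of Mock-LLC tumour 4 gave 28 while most other libraries left out gave 1.

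Markers of other cells that the gates could hold were measured in every library. The median over 13 T cell genes was at most 0.106 CPM in any library but 1, and the same held for 9 NK cell genes at 0.0385 and 8 B cell genes at 0.178 CPM. The exception was the SULT2B1b-LLC tumour 1 Ly6Chigh library, with 0.757, 0.379 and 6.44 CPM. For 7 endothelial genes it was 3.41 CPM there and at most 0.622 elsewhere. The erythroid median reached 4.76 CPM in 1 Mock-LLC Ly6Clow library and was 0 in the tumour 1 library, and that of epithelial or tumour genes reached 2.18 CPM. The eosinophil median was 21.1 ± 2.41 CPM in Mock-LLC and 35.1 ± 3.32 CPM in SULT2B1b-LLC Ly6Clow cells, and 0 and 0.379 ± 0.757 CPM in Ly6Chigh cells. The list of mast cell and basophil genes had a median of 5.30 CPM in the tumour 1 library and at most 1.45 CPM in any other. The fibroblast median was 35.6, 43.9, 5.84 and 31.1 CPM in the 4 SULT2B1b-LLC Ly6Chigh libraries. It was 3.72 to 25.5 CPM in the Mock-LLC ones and 2.04 to 4.63 CPM in Ly6Clow libraries. That of plasmacytoid dendritic cells was 9.09 CPM in the tumour 1 library and at most 5.70 CPM in any other. Neutrophil genes had a median of at most 1.51 CPM in any library.

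In the fit of all 15 libraries without a block, no list that passed had a median or mean log2 fold change of the other sign than its test. Without the tumour 1 library the tumour-associated macrophage list passed downward in Ly6Clow cells with the preset correlation, with a median of 0.05. Among lists that did not pass, the median, mean and test differed in sign for neutrophils, monocytes, tumour-associated macrophages and the unfolded protein response between tumour types in Ly6Chigh cells, and for tumour-associated macrophages, the unfolded protein response and chemokine receptors in Ly6Clow cells. Between populations they differed for chemokine receptors, neutrophils and the unfolded protein response in Mock-LLC and for hypoxia in SULT2B1b-LLC tumours, and in the interaction for complement, LXR targets, the unfolded protein response and both conventional dendritic cell lists.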

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

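The test for background reads in the Ly6Chigh library of SULT2B1b-LLC tumour 1 was set before its result was seen. The tests of other cells, of gate carry-over and of other splits of the samples were chosen only after the results were seen. For both gate tests the share that picks the genes was raised to 10 percent after the first outcome had been seen, and for Ly6Clow cells the genes were then picked from Mock-LLC Ly6Chigh cells. The side on which both gate tests fell was the same before. For the test of other cells the lists and the rule were widened after its first outcome had been seen, which left open what the first rule had excluded.

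In groups of 4 libraries a sample was singled out when its gap to the nearest other, divided by the whole range, exceeded Dixon's critical value, which chance exceeds in about 1 of 20 groups. Of 295 groups of values tested, 277 were of named genes and gave 16 samples, where chance gives about 14. In the other 18, of library measures, the number of genes with a count (gap 0.916) and the percent of counts on unnamed gene models (gap 0.984) singled out the Ly6Chigh library of SULT2B1b-LLC tumour 1.

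That library had 24540 genes with a count, against 14002 to 14888 in the rest of its group. Reads from genomic DNA or other background fit the values they predict: 52% of 1409 olfactory receptor genes had a count, against at most 5.75% in any other library. Over the 5400 genes counted in that library alone counts rose with exon length (Spearman rho 0.36, across genes), and of 21130 genes silent in all other libraries 13.2% of the shortest and 60.4% of the longest of 4 equal length classes were seen. Background reads are thus a candidate explanation, and no biological explanation was tested, since no group of the design sets this tumour apart. RNA of another cell type stays open beside it: of 11 lists of other cells 7 had a higher median there than in every other library, the highest at 9.09 CPM for plasmacytoid dendritic cells, then 6.44 CPM for B cells.

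In Ly6Clow cells of SULT2B1b-LLC tumours interferon-gamma and MHC class II genes were higher, which Ly6Chigh cells in the Ly6Clow gate could also give. The H2-Aa rise of 3940 CPM would need a share of 77.9% such cells. The test had 2 genes, Ly6c2 at 0.0223% and Plac8 at -2.26% (median -1.12%). Ly6c2 encodes the Ly6C marker of the sort, so its low share was largely set by the gate. That leaves Plac8, which argues against this as far as 1 gene can. B cells are argued against too: the highest of Cd79a, Cd79b and Ms4a1 reached 0.35% of the H2-Aa rise. That was Cd79b, at 13.8 ± 2.30 against 4.91 ± 0.750 CPM (adjusted p = 0.538), which was added to this test later and did not change its side. A shift in the make-up of the Ly6Clow cells also stays open and was not tested. With camera and an estimated correlation, the lists of macrophages (adjusted p = 0.00474) and conventional dendritic cell 1 (adjusted p = 0.00187) were higher there. That of monocytes was lower (adjusted p = 0.00395). An effect of SULT2B1b on the tumour and its interferon level, or on the cells, stays open and was not tested either.

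In Ly6Chigh cells of SULT2B1b-LLC tumours the macrophage list was higher with the preset correlation (4 of 11 members past the threshold; adjusted p = 0.0519 with an estimated correlation), which Ly6Clow cells carried over might give. C1qa would need a share of 28.7%, and the 10 genes high in Ly6Clow and low in Mock-LLC Ly6Chigh cells implied a median of 3.95% (2.31% over 7 genes at the first limit). This argues against Ly6Clow cells, carried over as sorted, as the source of the C1qa rise, while a small share of them stays open. The shares ran from -0.655% for G0s2 to 43.8% for Ccl8, with Olfml3 at 37.2%, Cbr2 at 23.5% and Gas6 at 16% but Alox15 at 2.31% and Retnlg at 1.01%. Carry-over of only a macrophage part of the Ly6Clow cells stays open, as does a change within Ly6Chigh cells.

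Among genes in Mock-LLC tumours the gap was 1 for Alox15 in Ly6Chigh replicate 4 (0.362 CPM, the others 0) and 1 for Siglecf in Ly6Chigh replicate 4 (1.90 CPM, the others 0). It was 0.908 for Thbs3 in Ly6Clow replicate 4, 0.854 for Plac8 in Ly6Chigh replicate 3, and 0.851 for Serpinb2 and 0.845 for Zbp1 in Ly6Chigh replicate 2. In SULT2B1b-LLC Ly6Chigh cells it was 0.857 for Acadl and 0.9 for Birc5 in replicate 4. There it was also 0.855 for Ccr3 and 0.901 for Ly6c1 in replicate 2, and 0.882 for Ifi47, 0.866 for Itgam, 0.93 for Hspa1b and 0.86 for Spp1 in replicate 1. In the same group the gap was 1 for Prg2 in replicate 2 (1.49 CPM, the others 0) and 1 for Cxcr2 in replicate 4 (0.104 CPM, the others 0). Spp1 stood at 274 CPM in replicate 1 and at 747 to 880 CPM in the others.

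The effect of SULT2B1b differed between populations by the interaction test for Thbs3 (10.64 on the log2 scale, fitted against a group at 0) and Alox15 (5.66). It differed for 12 lists with the preset correlation. The effect was lower in Ly6Chigh cells for interferon-gamma (adjusted p = 7.01e-10), MHC class II (adjusted p = 2.95e-08), type I interferon (adjusted p = 3.3e-05), dendritic cell maturation (adjusted p = 0.000186), mitochondrially encoded (adjusted p = 0.00261), immediate-early (adjusted p = 0.00436) and MHC class I genes (adjusted p = 0.0061). Only Ly6Chigh cells were sorted for MHC-II, so their class II effect is measured in cells held to that marker, and gate and effect are not separated. The effect was higher in Ly6Chigh cells for fibroblasts (adjusted p = 7.01e-10), ribosomal proteins (adjusted p = 0.000108), hypoxia (adjusted p = 0.00108), oxidative phosphorylation (adjusted p = 0.00261) and monocytes (adjusted p = 0.00468). With an estimated correlation the interferon-gamma and fibroblast lists passed (adjusted p = 0.0496 each), MHC class II had adjusted p = 0.0806 and the other 9 lists 0.218 to 0.543. Without the SULT2B1b-LLC tumour 1 library MHC class I (adjusted p = 0.0572) and immediate-early genes (adjusted p = 0.23) no longer passed with the preset correlation. With the tumour as a block 0 genes passed, and the interferon-gamma and fibroblast lists had adjusted p = 0.221 with an estimated correlation. With that block tumour-associated macrophage genes passed with the preset correlation (adjusted p = 0.0332, against 0.306 without it), but not with an estimated one (adjusted p = 0.407).

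Each comparison was repeated for all 35 splits of its libraries into groups of the same sizes. For the gene counts between tumour types 1 split, the real one, gave as many in Ly6Chigh cells (223, highest other 68) and in Ly6Clow cells (88, highest other 0). With 35 splits, 1 is the smallest number possible, and there was no adjustment for the number of results judged. Such a count makes chance less likely but does not exclude it. The 2 interaction genes were reached by 3 splits, the real one among them (highest other 6). For lists 1 split, the real one, gave as many in Ly6Chigh cells (15, highest other 14) and for the interaction (12, highest other 10), both narrowly. The 19 lists of Ly6Clow cells were reached by 2 splits, the real one among them (highest other 19). With an estimated correlation the highest other was 1, 10 and 0 where the real split gave 4 lists in Ly6Chigh cells, 12 in Ly6Clow cells and 2 for the interaction. Between populations the libraries are paired by tumour, and the 8 splits that part as many pairs as the real one are too few for a share under 0.05. There the real split gave 1160 genes (highest other 0) and 19 lists (highest other 15) in Mock-LLC, and 365 genes (highest other 70) and 15 lists (highest other 13) in SULT2B1b-LLC tumours, so that 1 split, the real one, gave as many each time. The other splits leave 1 or more tumours with both libraries on the same side, and of all 35 in SULT2B1b-LLC 3 gave as many lists (highest other 16). For the correlation of effects between populations 1 split, the real one, gave as high a value (0.0914, highest other 0.0861). The margin is narrow, so chance is not excluded. The value had an SD of 0.0359 with libraries left out in turn and was -0.00688 without SULT2B1b-LLC Ly6Clow replicate 4.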

How the results depend on the processing

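Fits without the Ly6Chigh library of SULT2B1b-LLC tumour 1 for every comparison, alone or with quality weights, were chosen only after the data were seen; the other alternatives were planned. The counts of genes changed were 223 and 88 between tumour types in Ly6Chigh and Ly6Clow cells, 1160 and 365 between populations in Mock-LLC and SULT2B1b-LLC tumours, and 2 for the interaction. They are given below in this order. Median-ratio, upper-quartile and no scaling factors, the stricter filter and non-robust settings left all 5 counts within 1.5 times these. In every alternative run no gene called here took the other sign.

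With no filter on low counts 109, 63, 605, 204 and 1 genes passed, from a test of more genes. DESeq2 gave 992, 193, 1874, 887 and 109. Limma-voom gave 201, 250, 2433, 652 and 4, and with quality weights 19, 703, 1511, 719 and 0 (1277 at an unadjusted p under 0.05). Fits of the 2 groups compared gave 3, 422, 1023 and 246, with 3, 88, 828 and 192 of the same genes. An adjusted p under 0.01 left 33, 44, 452, 155 and 1, and a 2-fold minimum 137, 56, 633, 232 and 2, by construction. In edgeR a block for the replicate number, which across tumour types is only a shared number, gave 0 in Ly6Chigh cells (809 at an unadjusted p under 0.05) and 166 in Ly6Clow cells. A block for the tumour gave 1028 and 210 between populations and 0 for the interaction (1095 at an unadjusted p under 0.05). Without the SULT2B1b-LLC tumour 1 Ly6Chigh library the counts were 348, 107, 1433, 421 and 3, and with quality weights as well 20, 679, 1366, 674 and 3. Fits of the 2 groups compared do not share the spread with the other population. They moved the tumour counts in opposite directions, to 3 in Ly6Chigh and 422 in Ly6Clow cells. Replicates correlated at 0.733 to 0.865 in Ly6Chigh and 0.962 to 0.975 in Ly6Clow groups, so the 223 rest on a spread shared with less variable libraries. These fits also had fewer libraries and their own filter, which was not separated. Otherwise, apart from the filter and thresholds, the cause was not tested.

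With each library left out in turn the counts ran from 120 to 358, 41 to 68, 584 to 1134, 127 to 421 and 1 to 28. The lowest and highest came, in this order, without Mock-LLC Ly6Chigh replicates 3 and 4, without SULT2B1b-LLC Ly6Clow replicate 2 and Mock-LLC Ly6Clow replicate 4, without Mock-LLC Ly6Clow replicate 2 and Ly6Chigh replicate 4, and without SULT2B1b-LLC Ly6Clow replicate 4 and Ly6Chigh replicate 1. For the interaction 28 came without Mock-LLC Ly6Chigh replicate 4.

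Lists past the threshold numbered 15, 19, 19, 15 and 12 with the preset correlation, and 4, 12, 8, 8 and 2 with an estimated one. By fry, which tests each list alone, there were 15, 11, 20, 14 and 3. The correlation of effects was 0.0914, 0.221 over genes with an average log2 CPM of 3 or more, and -0.00688 to 0.115 with a library left out; the lowest came without SULT2B1b-LLC Ly6Clow replicate 4 and was the only one of the other sign.

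Of the named genes, those that took the other sign had not passed the threshold; their log2 fold changes follow, with the range when libraries are left out. Ly6c2 between tumour types in Ly6Clow cells (0.02) was at -0.06 with quality weights and with the number block. It was at -0.06 and -0.09 without Mock-LLC Ly6Clow replicates 1 and 2, and at -0.1 and -0.04 without SULT2B1b-LLC Ly6Clow replicates 2 and 3 (range -0.1 to 0.22). Trem1 between populations was at -0.08 with quality weights and -0.02 without Ly6Chigh replicate 1 in Mock-LLC (range -0.02 to 0.2), and at -0.01 without Ly6Chigh replicate 4 in SULT2B1b-LLC (range -0.01 to 0.61). In SULT2B1b-LLC Cd74 was at 0.03 without Ly6Clow replicate 4 and at 0.03 without Ly6Chigh replicate 1 (range -0.22 to 0.03), where H2-Eb1 was at 0.04 (range -0.21 to 0.04). Itgam between tumour types in Ly6Chigh cells was at 0.01 without SULT2B1b-LLC Ly6Chigh replicate 1 (range -0.26 to 0.01). The cause was not tested.

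Of 181 calls of named genes, quality weights lost 39, no filter 36, limma-voom 17, and each other method that tested all of them at most 7 (leaving out libraries aside). Fits of the 2 groups compared lost 44 of the 177 calls they tested, the number block 40 of 69 and the tumour block 12 of 112. Depth was lower in Ly6Chigh libraries, at 2617878 to 10626954 counts against 19792494 to 39284008 in Ly6Clow libraries, and its effect on the calls was not tested.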

Other observations

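The tests in this part were chosen only after the results were seen. Fibroblast genes were higher as a list in Ly6Chigh cells of SULT2B1b-LLC tumours with the preset correlation, but not with an estimated one (adjusted p = 0.0728), and fibroblast RNA carried over into the gate may give this. Of the 9 measured genes 2, Dcn and Pdgfra, passed the threshold upward. The median log2 fold change over the list was 1.55. The rule took 7 genes past the threshold as a sign of carry-over, and a median at or under 0 as a sign against it. Neither was met. The simulated fit recovered 28% of 2-fold and 70% of 4-fold changes in Ly6Chigh cells, so falling short of 7 does not argue against carry-over. Dcn stood at 195 ± 59.1 CPM and Col3a1 at 711 ± 269 CPM (n = 4). The cells as sorted for CD11c and MHC-II thus held such transcripts. Carry-over of fibroblast RNA stays open, and RNA of tumour cells was not told apart from it. The rises of Pcolce and Thbs3 in Ly6Chigh cells were not tested for such carry-over, so they need not be changes within myeloid cells.

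SULT2B1b sulfates oxysterols, so lower oxysterol activity at LXR in both populations could be a hypothesis for the sterol genes. It predicts LXR targets lower in SULT2B1b-LLC tumours, whereas the list was higher in Ly6Clow cells (adjusted p = 0.0174 with an estimated correlation), with Pltp higher in both populations. In Ly6Chigh cells the list did not pass with an estimated correlation (adjusted p = 0.174). In Ly6Clow cells 2 of 18 members passed, Pltp and Apoe. Apoe is also on the macrophage list, which rose there too (adjusted p = 0.00474). The rise in Ly6Clow cells goes against the prediction, but cell composition and targets shared with other factors were not told apart. Cholesterol synthesis genes were higher in both populations (adjusted p = 7.36e-05 in Ly6Clow and 0.0401 in Ly6Chigh cells), which the prediction does not cover. The hypothesis stays open.

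Mitochondrially encoded genes took 3.67 ± 0.976% of counts in Mock-LLC Ly6Chigh cells, 2.00 ± 0.194% in SULT2B1b-LLC Ly6Chigh cells, 2.23 ± 0.238% in Mock-LLC Ly6Clow cells and 1.84 ± 0.188% in SULT2B1b-LLC Ly6Clow cells.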
